A study of Mus musculus with 4 samples.

How the data were processed

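Gene expression was measured by sequencing total RNA from primary mouse oligodendrocytes after 5 days in differentiation medium, in 2 Control and 2 Sp7KO libraries. Groups and replicate numbers were taken from the titles of the samples, and columns were assigned to samples by the genotype and replicate number in their names, where WT stands for Control as in the design text. The labels' protocols name a kit for total RNA libraries and an Illumina HiSeq instrument.

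The deposited table holds raw whole-number counts per gene and library, made by the authors with Trim Galore 0.6.7, cutadapt 3.4, STAR 2.7.10a, Picard, SAMtools and featureCounts on build mm10, per the submitters' processing notes, which give neither the order of the tools nor their settings and also name DESeq2. Another column deposited by the authors gives the summed exon length of each gene in bases. The strand setting, the gene annotation, the read layout and whether duplicate reads were removed are not given in the sources used here. Removal of duplicates would limit the count of abundant genes. Without a known strand setting, reads of genes that overlap on opposite strands cannot be told apart, and reads shared by near-identical genes may be lost or split.

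The table lists 55471 genes by Ensembl identifier. A symbol was found for 55144 of them, and the 327 without one held 0.034% of the counts. Of 55230 genes found in GENCODE M21, an annotation of the same build, 54937 had the same start and end. Coordinates are those of the count table, and biotype and GC content came from GENCODE M21. No row without a gene was present, and 0 columns belonged to other series.

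Library totals ranged from 10493142 to 11672895 counts, a narrow range, and counts are not independent molecules, so the intervals given for Sp7 cover counting error only. Replicates were compared by a chi-square test of counts over genes with at least 20 counts in a pair, which measures excess over counting noise only and cannot show that they are separate cultures. Each library was kept as 1 replicate, as labelled.

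Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10, libraries were scaled by TMM (factors 0.991 to 1.01), and the groups were compared by the quasi-likelihood test (glmQLFit and glmQLFTest) with group as the only term. Adjusted p-values are Benjamini-Hochberg values over the 19827 tested genes, and genes with an adjusted p below 0.05 were called. An "edgeR adjusted p" always refers to this test. Log2 fold changes are Sp7KO minus Control, standard errors were derived from the fold change and its F statistic, and levels are TMM-scaled CPM with the SD of 2 libraries. The common biological coefficient of variation was 0.0302. For Sp7, which fell below the filter, summed counts were compared by an exact binomial test against the library totals.

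Before the data were examined, 23 gene lists (13 for the topic of the series and 10 for other cell types, cell states and sex-linked genes; 535 genes, 469 tested) were fixed, as were the main test and the other settings to try. Lists were tested by camera in limma 3.58.1 with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 23 lists, with an estimated correlation and fry as alternatives. With an estimated correlation camera uses only the residual degrees of freedom of the 4 libraries, so almost no list could be called. The rule for named genes, also fixed then, took Sp7 and Olig2, the 6 largest increases and 6 largest decreases among called genes with a mean log2 CPM of at least 1, no overlap between groups and a symbol that is not a predicted gene, the 3 called members with the smallest adjusted p of each topic list, and 1 of each other list. It gave 57 genes, some of which are not reported here. Members named besides these to complete a small count were chosen after their values were seen. Exons of 19 of the 57 overlapped another gene of the table. Values are called uncertain where that gene had more counts.

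The test was tried on simulated counts for the 19827 genes with 50 genes changed at each of 4 fold sizes. EdgeR recovered 16 of 50 genes at 1.25-fold, 31 at 1.5-fold, 39 at 2-fold and 47 at 3-fold, with 6 false calls. DESeq2 1.42.0 recovered 9, 28, 35 and 43, with 0 false calls. With no gene changed edgeR made 1 call. Counts were drawn with edgeR's own dispersion estimates for these libraries. The rates hold for that spread, which may be technical, and cannot show false calls from variation between cultures or animals. Using edgeR's estimates may also favour edgeR over DESeq2. Under these settings small changes were often missed, by DESeq2 more than by edgeR.

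Settings fixed in advance were DESeq2, limma-voom, other scalings (RLE and upper quartile), no filter on low counts, a stricter filter (CPM of 1 or more in 2 libraries), the replicate number as a block, leaving out each library in turn, and a fold change of at least 2. After seeing the data, 3 more were added: a correction for occupied start positions, in which a count c of a gene of L exonic bases became -L ln(1 - c/L), leaving out 5 genes at 0.99 reads per base or more; removal of each library's trend with GC content and reads per base by lowess (span 0.3); and autosomal genes only.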

Results

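The series profiled primary oligodendrocytes, the myelin-forming glia of the central nervous system, cultured from mouse brain. Progenitor cells were grown in a defined medium with PDGF-AA (10 ng/ml), neurotrophin-3, forskolin and CNTF. Differentiation was then started by taking PDGF-AA away and adding triiodothyronine (40 ng/ml), and the cells were collected on day 5. Control cells carried loxP-flanked Sp7 alleles without Cre. Sp7KO cells carried the same alleles with Olig2-Cre, a recombinase expressed from the locus of the oligodendrocyte transcription factor Olig2. Sp7, also called Osterix, is a zinc-finger transcription factor best known from osteoblasts. The single comparison of the series asks which genes differ without Sp7, with matrix genes and genes of the node of Ranvier as the stated interest. Cre at the Olig2 locus was present in Sp7KO cells only, so its effects cannot be told apart from a loss of Sp7.

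Total RNA of 4 libraries was sequenced, 2 per group, and gene counts were analysed. The counts assigned to genes summed to 10580950 and 11672895 in Control replicates 1 and 2, and to 11075847 and 10493142 in Sp7KO replicates 1 and 2. Between 29908 and 30938 genes had at least 1 count in a library. The labels do not say whether the libraries of a group came from separate animals or cultures, so p-values measure only the spread between these libraries, which may be technical. Counts of replicates differed by more than counting noise alone would give, with a chi-square per degree of freedom of 1.65 in Control and 1.51 in Sp7KO against 4.82 to 6.39 between groups. The correlation of log2 CPM (library-size scaled counts) across genes was 0.994 within Control, 0.993 within Sp7KO and 0.984 to 0.987 between groups. The first principal component held 63.8% of the variance and separated the groups.

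Sp7 (ENSMUSG00000060284, chromosome 15, 102356606 to 102367182, minus strand, mm10; 3398 exonic bases) was close to undetected in every library. It had 2 and 2 counts in Control replicates 1 and 2, and 6 and 1 counts in Sp7KO replicates 1 and 2. That is 4 of 22253845 counts in Control and 7 of 21568989 in Sp7KO, a ratio of 1.81 with an exact 95% interval of 0.459 to 8.41 (two-sided exact binomial test, p = 0.381). The interval covers counting error only, and it compares reads of these libraries. Sp7 was too low for the test across genes, and a loss of its transcript was not detectable at this depth, so the targeted gene could not check the labels. Counts of whole genes would also include any transcript left outside the deleted part. Olig2 had 1789 and 1941 counts in Control and 1976 and 2007 in Sp7KO, a log2 fold change of 0.15 (SE 0.05, edgeR adjusted p = 0.0530) that was not called. Over the alternative settings its adjusted p ran from 0.00707 to 0.315, and it was called without Control replicate 1 (adjusted p = 0.0263), with no filter on low counts (adjusted p = 0.0339) and with a correction for occupied start positions (adjusted p = 0.00707), where its log2 fold change was 0.27.

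Of the 19827 genes tested, 2373 differed between Sp7KO and Control by edgeR's quasi-likelihood test with a Benjamini-Hochberg adjusted p below 0.05. Expression was higher in Sp7KO for 1206 of these and lower for 1167. Among called genes with a mean log2 CPM of at least 1, no overlap between the groups and a symbol that is not a predicted gene, the largest increases were in Ceacam20, a cell adhesion molecule of the carcinoembryonic antigen family (13.2-fold), Ppp1r14a, an inhibitor of myosin phosphatase (10.2-fold), the matrix glycoprotein Tnxb (8.46-fold), the tumour necrosis factor receptor Tnfrsf1b (8.25-fold), the zinc-finger gene Zfp804a (7.05-fold) and the axoglial adhesion molecule Cntn2 (7.02-fold). The largest decreases under the same limits were in the adaptor gene Grap2 (7.70-fold), Clca3a2 (7.57-fold), the cartilage collagen Col2a1 (6.55-fold), the phosphodiesterase Pde11a (6.36-fold), Pramel3 (5.75-fold) and the receptor gene Gpr15 (5.75-fold). Leaving out 1 library moved 4 of these folds by more than 1.5 times: Tnxb (5.21 to 19.5), Grap2 (5.43 to 12.9), Pramel3 (3.78 to 11.5) and Gpr15 (4.24 to 8.77). Grap2, Clca3a2 and Pramel3 had means below 1 CPM in Sp7KO, and Ceacam20 (0.635) and Tnfrsf1b (0.801) had means below 1 CPM in Control. Values of Ceacam20, Clca3a2 and Pramel3, which have close family members, and of Gpr15, whose exons overlap the more abundant Cpox on the other strand, are uncertain.

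Most changes were small. The median size of a called log2 fold change was 0.485, 1384 of the called genes (58.3%) changed by less than 1.5-fold, and 515 changed at least 2-fold, 172 higher and 343 lower in Sp7KO. In 10458 genes (52.7%) both Sp7KO libraries lay on the same side of both Control libraries, where chance gives 33.3%. DESeq2 called 1018 genes, 1017 of them also called by edgeR, with 520 higher and 498 lower. Without Sp7KO replicate 1, the number of genes called lower was 746.

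**Figure D1:**
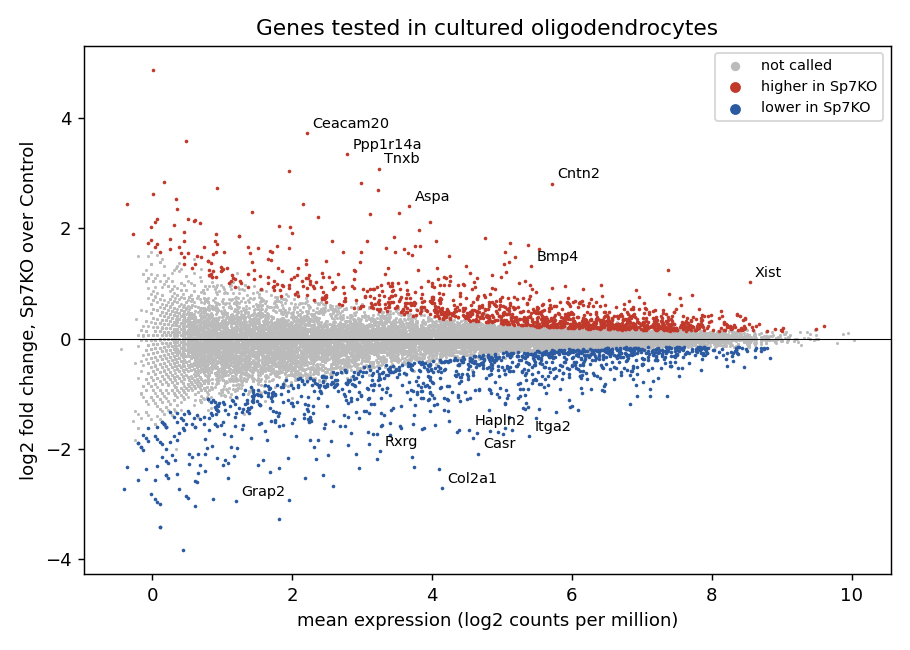
Log2 fold change of Sp7KO over Control (vertical axis) against mean expression in log2 CPM (horizontal axis) for the 19827 genes tested, 1 point per gene, with 1206 genes called higher in Sp7KO in red, 1167 called lower in blue and genes not called in grey. Fold changes narrow toward high expression, where Xist (log2 fold change 1.03) stands apart.

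Genes of the sex chromosomes differed between the groups as well. Xist, the RNA that silences one X chromosome in female cells (ENSMUSG00000086503, X, 103460366 to 103483254), was 245 ± 9.38 CPM in Control and 499 ± 2.36 CPM in Sp7KO (SD, n = 2 each), a 2.04-fold rise (edgeR adjusted p = 4.247e-08). Of the 5 tested sex-linked genes Xist rose and the Y-linked genes Kdm5d, Uty, Eif2s3y and Ddx3y fell, with the same counts adjusted over the list alone. Ddx3y fell from 109 ± 2.83 to 81.5 ± 0.794 CPM. Camera, which tests a list against all other genes, did not call this list (adjusted p = 0.0774; 0.521 with an estimated correlation) except with no filter (adjusted p = 0.00538), without Control replicate 2 (adjusted p = 0.0375) and without Sp7KO replicate 1 (adjusted p = 0.0047), in a range of 0.0047 to 0.185 with the preset correlation. Xist and the Y-linked genes move in opposite directions with sex, so a list test of a shared direction cannot decide on sex make-up. Of the called genes 2284 were autosomal, 81 lay on the X and 5 on the Y chromosome. This difference held between the same libraries as every gene group described here.

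Among genes of the node of Ranvier and the flanking paranodes and juxtaparanodes, adhesion molecules rose more often than they fell. Cntn2, an immunoglobulin-family adhesion molecule of juxtaparanodes (ENSMUSG00000053024, chromosome 1, 132509427 to 132543256), rose from 13.1 ± 1.63 to 92.5 ± 15.2 CPM (SD, n = 2 each), with a log2 fold change of 2.81 (SE 0.12, edgeR adjusted p = 4.247e-08). L1cam, another adhesion molecule of this family, rose 1.87-fold, from 20.7 ± 1.38 to 38.7 ± 4.0 CPM. Nectin1 fell 1.19-fold, from 214 ± 1.73 to 180 ± 1.71 CPM. Of 29 genes for axoglial adhesion and its cytoskeletal partners, 8 rose, 2 fell (Nectin1 and the potassium channel gene Kcna2) and 19 were not called, and adjusted over the list alone 9 were higher and 3 lower. Camera placed the list above other genes (median log2 fold change 0.11, adjusted p = 0.000174; adjusted p = 0.521 with an estimated correlation). With so few libraries almost no list could pass with an estimated correlation.

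Genes of the matrix around nodes went both ways. Hapln2, a link protein that binds hyaluronan in the nodal matrix (ENSMUSG00000004894, chromosome 3, 88021750 to 88027583), fell 3.16-fold, from 34.5 ± 2.50 to 10.9 ± 0.278 CPM (SD, n = 2 each; log2 fold change -1.66, SE 0.10, edgeR adjusted p = 6.245e-07). The glycoprotein Tnc fell 1.91-fold, from 33.0 ± 4.53 to 17.4 ± 2.86 CPM, and the proteoglycan Vcan rose 1.33-fold, from 242 ± 4.12 to 323 ± 16.2 CPM. Of 18 tested genes for perinodal and perineuronal matrix, 4 rose (Vcan, Tnr, Hapln4 and Omg), 2 fell (Hapln2 and Tnc) and 12 were not called, and adjusted over the list alone 5 were higher and 2 lower. As a whole the list was not called (camera, median 0.09, adjusted p = 0.256; 0.521 with an estimated correlation). It was called when genes were not filtered on low counts (adjusted p = 0.0113; range with the preset correlation 0.0113 to 0.427).

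**Figure D2:**
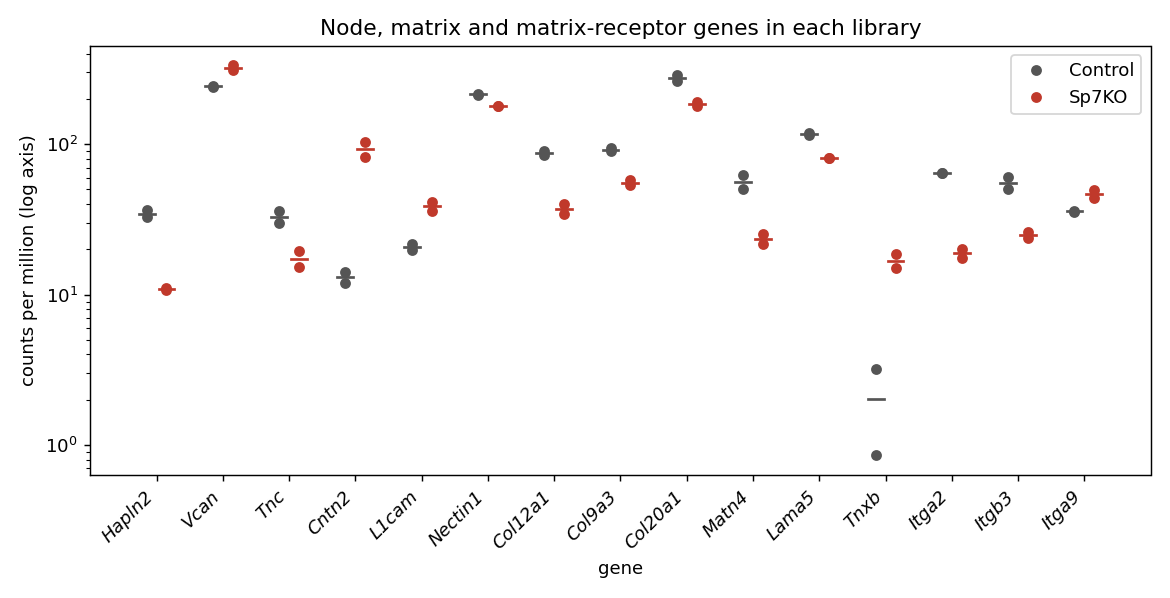
Levels in CPM on a log axis (vertical) for 15 node, matrix and matrix-receptor genes (horizontal), with 1 point per library, Control in grey and Sp7KO in red, and a bar at the mean of the 2 libraries of each group. Both Sp7KO libraries lie on the same side of both Control libraries for each gene, as for Cntn2 (13.1 against 92.5) and Itga2 (64.1 against 18.8).

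Collagen genes fell more often than they rose. Col12a1, a collagen that decorates fibrils, fell 2.36-fold, from 87.6 ± 4.47 to 37.2 ± 4.08 CPM (SD, n = 2 each; edgeR adjusted p = 5.064e-07). Col9a3 fell 1.66-fold and Col20a1 1.49-fold, and Col2a1 (ENSMUSG00000022483, chromosome 15, 97975602 to 98004695) went from 29.5 ± 11.7 to 4.52 ± 0.716 CPM. Col2a1 lies within 5 Mb of the engineered Sp7 locus. Col6a2 rose 3.41-fold and Col6a1 3.19-fold, larger changes than these falls except that of Col2a1. Of 28 tested collagen chains 7 fell, 5 rose (Col6a1, Col6a2, Col5a2, Col23a1 and Col9a1) and 16 were not called, and adjusted over the list alone 10 were lower and 5 higher. Camera placed collagens below other genes (median -0.16, adjusted p = 0.000243; adjusted p = 0.521 with an estimated correlation). Without Control replicate 2 the list was not called (adjusted p = 0.133; range with the preset correlation 5.68e-08 to 0.133) and its median was -0.02. Among fibroblast, pericyte and endothelial markers, Foxc1 rose from 1.63 ± 0.502 to 6.12 ± 0.127 CPM.

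Secreted matrix glycoproteins changed in both directions to a similar extent. Matn4, a matrilin of progenitor cells, fell 2.41-fold, from 56.2 ± 8.58 to 23.4 ± 2.50 CPM (SD, n = 2 each; edgeR adjusted p = 7.204e-06). The laminin chain Lama5 fell 1.44-fold, from 117 ± 2.62 to 81.1 ± 0.646 CPM, and Tnxb rose from 2.04 ± 1.68 to 16.9 ± 2.65 CPM. Of 50 tested members 12 rose, 11 fell and 27 were not called, and adjusted over the list alone 15 were higher and 14 lower, with no call for the list (camera, median 0.04, adjusted p = 0.837; 0.850 with an estimated correlation).

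Genes that remodel matrix changed in both directions. The membrane-anchored metalloproteinase Mmp24 fell 1.65-fold (54.8 ± 5.44 to 33.2 ± 0.323 CPM; SD, n = 2 each), while the protease inhibitor Timp4 rose 1.32-fold and Mmp16 rose 1.26-fold. Of 32 tested proteases, inhibitors and cross-linking enzymes, 7 rose, 3 fell (Mmp24, Adamts4 and P4ha2) and 22 were not called, and adjusted over the list alone 8 were higher and 4 lower. The list was not called (camera, up, adjusted p = 0.256; 0.521 with an estimated correlation), and its median of 0.08 and mean of -0.02 differed in sign.

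Itga2, a collagen-binding integrin subunit (ENSMUSG00000015533, chromosome 13, 114833081 to 114932100), fell 3.41-fold, from 64.1 ± 0.244 to 18.8 ± 1.65 CPM (SD, n = 2 each), with a log2 fold change of -1.77 (SE 0.08, edgeR adjusted p = 4.247e-08). The integrin subunit Itgb3 fell 2.24-fold and Itga9 rose 1.31-fold. Of 21 tested integrins and other matrix receptors 3 fell (Itga2, Itgb3 and Itga7), 2 rose (Itga9 and Itga8) and 16 were not called, with the same counts adjusted over the list alone. Camera did not call the list (down, adjusted p = 0.151; 0.521 with an estimated correlation). Its median of 0.04 was positive and its mean of -0.08 negative. DESeq2 did not call Itga9 (adjusted p = 0.0683; range over alternatives 0.000131 to 0.0683).

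Several myelin genes rose while Hapln2 and Mbp fell. Ppp1r14a rose from 1.21 ± 0.0268 to 12.5 ± 2.24 CPM (SD, n = 2 each), and Aspa, the enzyme that cleaves N-acetylaspartate, rose 5.28-fold, from 4.10 ± 1.70 to 21.4 ± 1.34 CPM (edgeR adjusted p = 4.203e-06). Of 34 myelin genes 13 rose, 3 fell, among them Hapln2 and Mbp, and 18 were not called, and adjusted over the list alone 15 were higher and 4 lower. Camera placed the list above other genes (median 0.06, adjusted p = 4.91e-05; adjusted p = 0.613 with an estimated correlation). The median was 0.017 without Control replicate 2, 0.165 without Control replicate 1 and 0.125 without Sp7KO replicate 1, and the list was called in each case. Mbp, the basic protein of compact myelin, went from 422 ± 23.0 to 364 ± 39.7 CPM.

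Genes of newly formed oligodendrocytes and of progenitors were also higher more often than lower. Slc9a3r2, a scaffold gene, rose 2.99-fold, from 16.7 ± 0.160 to 49.8 ± 3.55 CPM (SD, n = 2 each; edgeR adjusted p = 2.825e-07), and the secreted ligand gene Bmp4 rose 2.48-fold, from 24.6 ± 1.45 to 60.7 ± 6.21 CPM. The calcium-sensing receptor Casr fell 4.25-fold, from 40.2 ± 0.819 to 9.50 ± 4.26 CPM. Of 22 genes of newly formed cells 9 rose, 5 fell (Casr, Cemip2, Frmd4a, Rras2 and Cnksr3) and 8 were not called, with the same counts adjusted over the list alone (camera, median 0.06, adjusted p = 0.00758; adjusted p = 0.521 with an estimated correlation). This call was lost without Control replicate 2 (adjusted p = 0.0633; range with the preset correlation 0.00106 to 0.0927) and with trends in GC content and abundance removed (adjusted p = 0.0927), where the median was 0.02. Among 22 progenitor genes 7 rose, Matn4 fell and 14 were not called, and adjusted over the list alone 14 were higher and 2 lower (camera, median 0.14, adjusted p = 1.88e-05; adjusted p = 0.521 with an estimated correlation), with a median of 0.08 and a kept call without Control replicate 2. Lrrtm3 rose 1.57-fold and Cspg4, the NG2 proteoglycan of progenitors, 1.45-fold.

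Among transcription factors of the lineage, Rxrg, a retinoid X receptor, had the largest change. It fell 4.11-fold, from 14.8 ± 2.27 to 3.60 ± 0.444 CPM (SD, n = 2 each; edgeR adjusted p = 1.023e-05). Nkx2-2 rose 1.40-fold and Sox6 1.20-fold. Of 31 factors 6 rose, 2 fell (Rxrg and Zfp536) and 23 were not called, and adjusted over the list alone 7 were higher and 3 lower. The list was not called (camera, up, median 0.05, adjusted p = 0.220; 0.521 with an estimated correlation), and its mean of -0.02 had the other sign.

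Most cholesterol synthesis genes rose, by small amounts. Lss, which makes lanosterol, rose 1.30-fold, from 309 ± 0.793 to 402 ± 11.9 CPM (SD, n = 2 each; edgeR adjusted p = 6.572e-05). Stard4, a sterol carrier, rose 1.33-fold. Of 25 genes 19 rose and the other 6 were not called, and adjusted over the list alone 22 were higher. DESeq2 called 12 of the 25, all higher. The fold change was positive in 24 of the 25, and camera gave this list its lowest adjusted p (median 0.26, adjusted p = 8.35e-16). With an estimated correlation the adjusted p was 0.521.

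**Figure D3:**
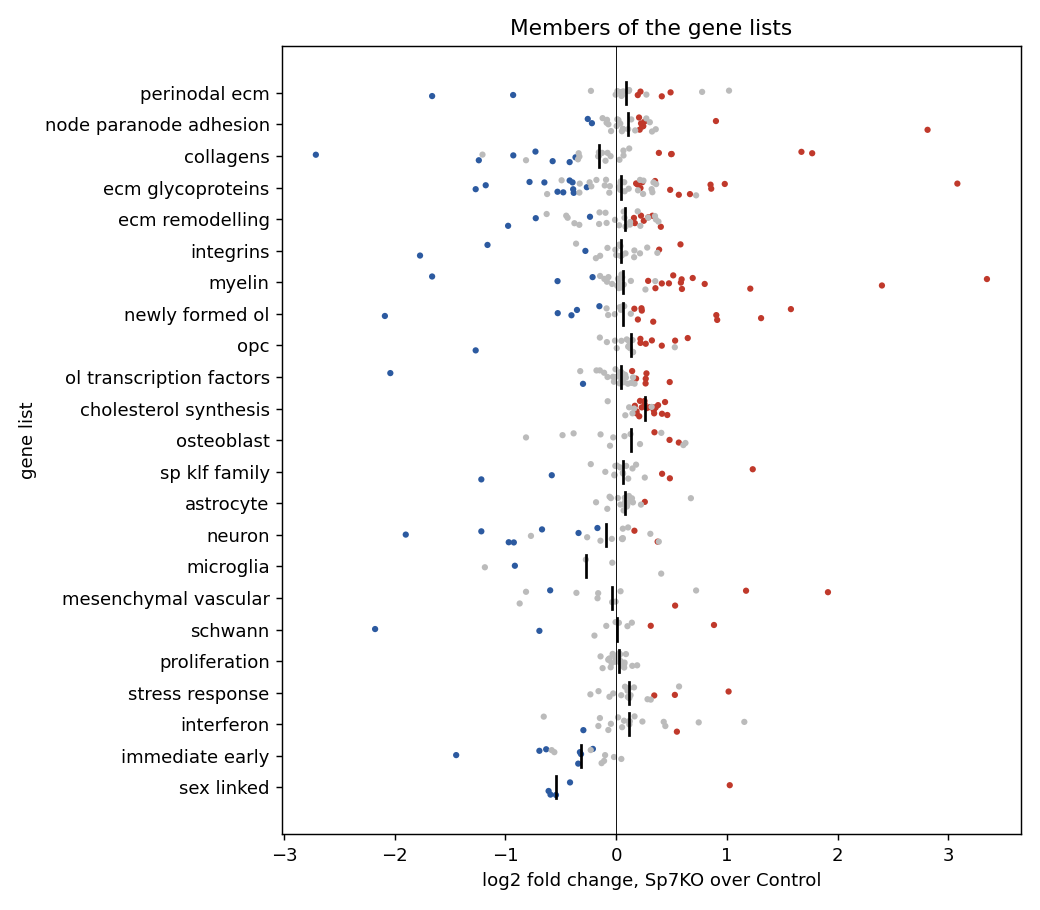
Log2 fold change of Sp7KO over Control (horizontal axis) for each tested member of the 23 gene lists (vertical axis), 1 point per gene, with called genes in red (higher) or blue (lower), genes not called in grey and a black bar at each list's median. In the cholesterol synthesis list 24 of 25 genes lie above 0.

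Of 30 genes of osteoblasts, the cells in which Sp7 is best known, 15 were expressed highly enough to test. The sphingomyelinase gene Smpd3 rose 1.40-fold, from 61.8 ± 1.37 to 86.4 ± 3.26 CPM (SD, n = 2 each; edgeR adjusted p = 9.209e-05), fibromodulin (Fmod) rose 1.48-fold and the alkaline phosphatase gene Alpl rose 1.27-fold. The other 12 were not called, and adjusted over the list alone 5 were higher. The list was not called (camera, median 0.13, adjusted p = 0.0774; 0.521 with an estimated correlation), but it was without Sp7KO replicate 1 (adjusted p = 0.0413; range with the preset correlation 0.0413 to 0.263), although its median was then 0.03. The call of Alpl was lost without Control replicate 2, without Sp7KO replicate 2 and with DESeq2 (adjusted p = 0.0798, 0.0711 and 0.390; lowest of its alternatives 0.0230).

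Among 19 tested Sp and Klf transcription factors, relatives of Sp7, 3 rose (Klf10, Klf8 and Klf2), 2 fell (Sp9 and Klf5) and 14 were not called, and adjusted over the list alone 6 were higher and 2 lower. Sp9 fell 2.33-fold, from 5.33 ± 0.302 to 2.29 ± 0.00627 CPM (SD, n = 2 each; edgeR adjusted p = 0.00287), while Klf10 rose 1.33-fold and Klf8 1.40-fold. Camera did not call the list (up, median 0.06, adjusted p = 0.223; 0.675 with an estimated correlation). DESeq2 called none of the 3 named factors (adjusted p = 0.0881 for Sp9, 0.128 for Klf10 and 0.137 for Klf8; lowest of their alternatives 3.36e-05, 6.09e-05 and 1.91e-06). The call was also lost for Klf10 without Sp7KO replicate 1 (adjusted p = 0.132) and for Klf8 without Control replicate 1 (adjusted p = 0.113). Exons of Sp9 overlap the more abundant Cir1 on the other strand, so its value is uncertain. Sp9 belongs to the neuron list too, where other members fell.

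Of 20 neuron markers 7 fell, among them the secreted glycoprotein Reln (1.27-fold, edgeR adjusted p = 0.000488), 2 rose (Map2 and Snap25) and 11 were not called, and adjusted over the list alone 8 were lower and 3 higher. The neuron list was not called (camera, median -0.09, adjusted p = 0.116; 0.675 with an estimated correlation) except without Control replicate 1 (adjusted p = 0.0318; range with the preset correlation 0.0318 to 0.472). Its median was -0.23 there and 0.01, of the other sign, without Control replicate 2. DESeq2 called 2 neuron markers lower and 1 higher. Of 20 astrocyte markers the bicarbonate transporter gene Slc4a4 rose 1.20-fold and 19 were not called, also adjusted over the list alone. The astrocyte list was not called (camera, median 0.08, adjusted p = 0.0774; 0.675 with an estimated correlation), but it was without Control replicate 1 (adjusted p = 0.000134), without Sp7KO replicate 1 (adjusted p = 0.0216) and with no filter (adjusted p = 0.00900), in a range of 0.000134 to 0.769 with the preset correlation. Its median was 0.15 without Control replicate 1 and 0.01 without Control replicate 2.

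Of 20 microglia markers 5 could be tested. The purinergic receptor P2ry12 fell 1.89-fold and 4 were not called, also adjusted over the list alone (camera, median -0.27, adjusted p = 0.220; 0.675 with an estimated correlation). P2ry12 was not called by DESeq2 (adjusted p = 0.0510; lowest of its alternatives 7.11e-06), and it overlaps the more abundant Med12l on the other strand. Of 13 tested fibroblast, pericyte and endothelial markers 3 rose (Cspg4, Foxc1 and Foxd1), Kdr fell and 9 were not called, also adjusted over the list alone. That list was not called (camera, up, adjusted p = 0.304; 0.675 with an estimated correlation), with a median of -0.04 and a mean of 0.11. Cspg4 belongs to the progenitor list too. Of 10 Schwann cell markers Ngfr and Cdh19 rose, 2 fell, among them Egr2, and 6 were not called, also adjusted over the list alone. The Schwann list was not called (camera, down, median 0.01, mean -0.17, adjusted p = 0.882; 0.934 with an estimated correlation).

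Of 15 tested immediate early genes, which respond within minutes to stimulation, 7 fell and 8 were not called, also adjusted over the list alone, and DESeq2 called 4 lower. Arc fell 1.55-fold, from 71.0 ± 8.52 to 45.7 ± 2.37 CPM (SD, n = 2 each; edgeR adjusted p = 0.000184). Camera placed the list below other genes (median -0.32, adjusted p = 0.000243; adjusted p = 0.521 with an estimated correlation). Its median was -0.19 without Control replicate 2. Stress genes lay above other genes as a list (camera, median 0.12, adjusted p = 0.0119; adjusted p = 0.521 with an estimated correlation). Hmox1, which degrades heme, rose 1.44-fold, Atf3 and Xbp1 rose and 15 of 18 were not called, and adjusted over the list alone 3 were higher and 1 lower. Of 19 interferon response genes Tap1 rose 1.46-fold, Irf9 fell and 17 were not called, also adjusted over the list alone (camera, median 0.12, adjusted p = 0.3; 0.747 with an estimated correlation). DESeq2 did not call Tap1 (adjusted p = 0.106; lowest of its alternatives 0.000313).

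No cell-cycle gene was called. Of the 25 tested, edgeR, DESeq2 and limma-voom each called 0, and 1 had an unadjusted p below 0.05. That gene, the centromere histone Cenpa, had a log2 fold change of -0.14 (SE 0.06, edgeR adjusted p = 0.177), and adjusted over the list alone 0 were called. The list was not called either (camera, median 0.03, adjusted p = 0.837; 0.934 with an estimated correlation). Over all 23 lists, camera called 8 with its preset correlation and 0 with an estimated correlation, where 1 had an unadjusted p below 0.05. With so few libraries almost no list could pass under the latter setting, so its 0 calls do not decide which lists moved. Leaving out 1 library in turn moved the median by more than 1.5 times, or turned its sign, in 4 of the 8 called lists and in 12 of the others. The sign turned in 6 lists, and camera called none of these. DESeq2 called fewer members of most lists than edgeR, such as 6 higher and 6 lower secreted glycoproteins and 2 higher and 5 lower collagens. Fry, which asks whether a list moves one way on balance, called 0 by direction, with 8 below an unadjusted p of 0.05, and 20 for change in either direction. The test for either direction asks whether members changed, not whether they changed more than other genes. Of all 19827 tested genes 4813 had an unadjusted p below 0.05 by edgeR, so the 20 does not set these lists apart.

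Fold changes were smaller where genes held more reads for their length. The largest absolute log2 fold change was 4.87 among the 2371 genes at or below 0.01 reads per exonic base, where counts are noisy. Among the 11 tested genes above 0.8 it was 0.14 and no gene was called. A maximum over so few genes tends to be smaller. The correction for start positions, which by its form widens the fold changes of such genes, kept 6 of the 11 and called 2 of them, Olig1 (log2 fold change 0.14 before and 0.30 after it, adjusted p = 0.0154) and Cldn11 (-0.04 and -0.26, adjusted p = 0.0384). Among called genes the median absolute log2 fold change was 0.22 for the 71 above 0.4 reads per base and 0.50 for the other 2302. Genes with few reads need larger changes to be called, so that gap comes in part from the threshold. The myelin gene Mbp took 0.0392% of the counts, and the 100 most abundant genes took 5.06% to 5.21%.

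**Figure D4:**
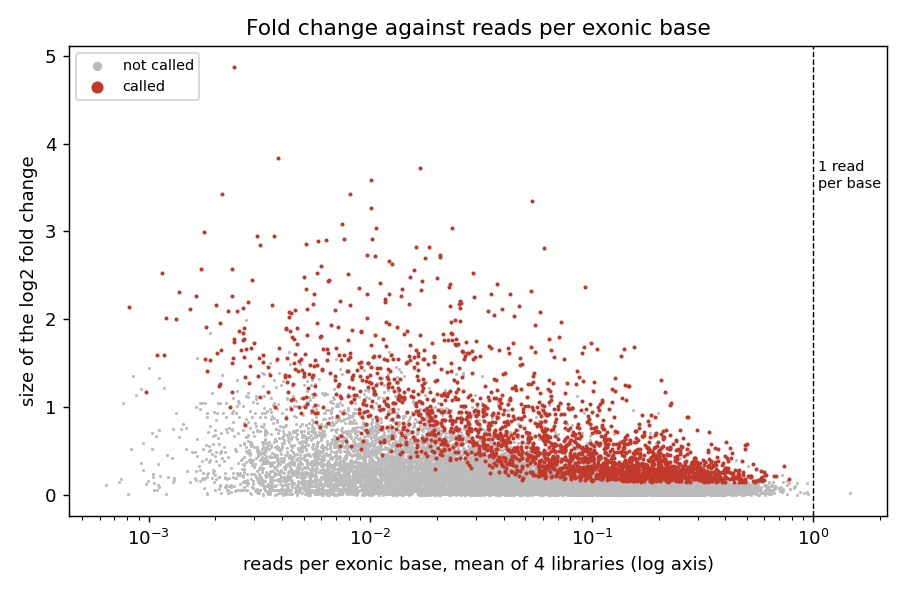
Absolute log2 fold change (vertical axis) against the mean number of reads per exonic base over the 4 libraries (horizontal axis, log scale) for each tested gene, with called genes in red, genes not called in grey and a dashed line at 1 read per base. Few genes reach the line, and the largest changes lie at low reads per base, up to 4.87, where counts are also noisiest.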

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

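The start-position correction, the removal of trends and the restriction to autosomal genes were chosen after the data were seen. The number of called genes stayed within 1.5 times of 2373 under all settings but 2: DESeq2 (1018 called, 520 higher, 498 lower and 249 at least 2-fold) and the requirement of at least 2-fold (515). No called gene changed sign under any setting. The start-position correction called 2353 genes (2280 shared), trend removal 2527 (2188 shared) and autosomal genes only 2280. DESeq2 also recovered fewer of the changes simulated with edgeR's dispersion estimates. Why it called fewer genes here was not tested further. Leaving out 1 library gave 1587 to 2823 called genes, and 746 to 1531 lower ones, the fewest without Sp7KO replicate 1; the lone library is then assumed to vary like the other group. With the replicate block, 2010 genes were called, and same-numbered libraries did not deviate together (correlation of deviations across genes 0.0062), so the numbers were not taken as pairs. Of the 23 lists 8 were called, 0 with an estimated correlation and 0 by fry. The estimates for the axoglial adhesion list (-0.0073) and the stress list (-0.00745) lay below the preset 0.01. Higher correlation therefore does not account for the lost calls of these lists. With an estimated correlation camera uses only the residual degrees of freedom of the libraries, where the preset setting draws on the number of tested genes. With 2 libraries per group almost no list could pass, so 0 calls under that setting cannot show that a list did not move. For the other lists the parts of this and of correlation were not separated. The log2 ratio of Sp7 was 0.84, and -0.92 to 1.61 over the leave-one-out settings, negative without Sp7KO replicate 1, so its sign rests on a single library with 6 counts. The first component held 64.9% under the stricter filter, which tests fewer genes. Over the alternatives, named genes kept their side of the threshold in 714 cases, lost it in 11 and gained it in 3. Lists kept it in 238 cases, lost it in 19 and gained it in 9, and 10 changed direction without a call on either side. Trend removal ended the call of newly formed oligodendrocyte genes (adjusted p = 0.0927). Sp7 could not be tested with voom, the block or the stricter filter, since it was filtered out. Depth limits low genes, where only large changes can pass, and reads per base may limit abundant ones.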

Other observations

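The correction for start positions, the trend removal and the tests of a swapped library, of autosomal genes against sex make-up, of reads per base and of the neighbourhoods of Sp7 and Olig2 were chosen after the results were seen, as were the genes of this paragraph and the next, so no enrichment was tested. Of 31 tested transcription factors of regional identity 6 were higher in Sp7KO, 5 lower and 20 not called by edgeR's quasi-likelihood test (Benjamini-Hochberg adjusted p below 0.05). The forebrain gene Six3 rose with a log2 fold change of 0.98 (SE 0.10) and its antisense non-coding neighbour Six3os1 with 1.62 (SE 0.07). Six3os1 and Six3 overlap on opposite strands and the strand setting is not stated, so both values are uncertain. Zic1 rose by 1.11, Pax3 by 2.09, Gsx1 by 0.53 and Emx2 by 0.41 on the log2 scale. Dlx1 fell by 0.97, Lmx1a by 0.90, En2 by 0.60, Meis2 by 0.28 and Otx1 by 0.28.

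Some other called genes are given as single cases. The alarmin Il33 rose from 3.84 ± 1.68 to 19.1 ± 2.65 CPM (SD, n = 2 each), the neurotrophic factor Gdnf from 3.74 ± 0.864 to 12.9 ± 1.20 CPM, and the choline transporter gene Slc5a7 from 2.47 ± 0.121 to 16.1 ± 1.41 CPM. The transcription factor Runx1 rose from 12.8 ± 3.43 to 31.9 ± 8.80 CPM. The Notch ligand Dll4 fell from 14.7 ± 1.54 to 3.23 ± 0.168 CPM, the melanin enzyme gene Dct from 52.9 ± 1.53 to 16.9 ± 1.39 CPM, and the neurofilament gene Prph from 27.9 ± 7.51 to 5.42 ± 0.304 CPM.

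The higher Xist and lower Y-linked genes of Sp7KO may come from a different share of male and female animals in the cultures. The X-linked genes Kdm6a, Kdm5c, Ddx3x and Eif2s3x, which escape inactivation, had a median log2 fold change of 0.103 (SE of the mean 0.024; 4 of 4 higher), as that explanation needs. A swapped library is argued against, since Xist differed by at most 0.088 (log2) within a group and by 1.014 between groups. A gene used in 1 sex alone was taken to lie between -0.73, the Y-linked gene that fell most less 2 SE, and 1.11, Xist plus 2 SE. In a one-sided t test with each gene's SE, adjusted over all 19173 tested autosomal genes, 84 of the 2284 called ones lay beyond those bounds (19 higher, 65 lower). For the other 2200 sex and genotype cannot be told apart. The bounds concern sex make-up alone. Any other difference between the cultures of the 2 groups, which the labels do not describe, cannot be told apart from genotype for the 84 either.

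The higher level of cholesterol synthesis genes is not accounted for by a trend with GC content and abundance, since the median log2 fold change was 0.235 with those trends removed against 0.257 before. It is not accounted for by a single library either, with a lowest median of 0.253 when each library was left out in turn. The list's call was lost, though, when the correlation among its members was estimated, at 0.225 (camera, adjusted p = 0.521), and with fry (adjusted p = 0.0681). Estimating the correlation also leaves camera only the residual degrees of freedom of the libraries, and it ended calls of lists whose estimate lay below the preset value. The lost call under that setting therefore cannot decide whether the cholesterol list moved. The difference may reflect genotype as a hypothesis, but sex make-up, which differed with the group, stays open, and no separate test of genotype was possible with this design.

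The small fold changes of abundant genes may come in part from reads being kept once per start position. Of 35165 genes with reads only 5 exceeded 1 read per exonic base in any library, the highest Gm26917 at 1.54 and the next at 1.06, as a limit of about 1 read per position needs. A correction for occupied positions widens the fold changes of dense genes by its form, so its result does not test this. How much of the pattern this explains was not measured, and a true lack of large changes among abundant genes was not tested.

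As a hypothesis, alleles linked to an engineered locus could add called genes nearby. Within 5 Mb of Sp7, 24 of 130 tested genes were called, Col2a1 among them, and 4.8% of windows of as many genes elsewhere held as many. Around Olig2 13 of 83 were called, and 22.4% of windows held as many. The share near Sp7 is one of 2 tested and unadjusted, and both groups carry the same floxed Sp7 alleles, so it does not separate them by design.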
